A study of Mus musculus with 8 samples.

How the data were processed

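Total RNA of mouse colon tumours was extracted with TRIzol and made into libraries with the NEBNext Ultra Directional kit, which marks strand, per the labels' protocols. The submitters' processing notes name HISAT2 and DESeq2, with no version, and the build GRCh38. GRCh38 is a human build, whereas the gene identifiers in the deposited table belong to the mouse C57BL/6NJ annotation, so coordinates are given as the table gives them and were not compared with any other build. Whether the authors counted reads by strand, and how reads shared by near-identical genes such as the immunoglobulin constant regions or ribosomal protein copies were assigned, is not given in the sources used here, so values of such genes are uncertain.

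One table was used. Per the file headers it holds, for each of 1428 genes, a normalized signal in each of 8 libraries (counts divided by size factors), the authors' group means, and the authors' log2 fold change of KO over WT, p-value and adjusted p-value. The deposited signal columns were compared with whole reads. For each library a size factor was found such that every value, times that factor, fell within 0.001 of a whole number, and 100% of values in each library did so. The size factors ran from 0.933 in KO replicate 2 to 1.12 in KO replicate 3. The recovered counts are thus derived from the deposited values, and they cover the listed genes alone. They sum to 1215820, 1259696, 1268646 and 1202677 reads in WT replicates 1 to 4 and to 1418923, 1316787, 1533770 and 2180787 reads in KO replicates 1 to 4. Library depth is not given in the sources used here, so no depth limit is stated.

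The design set before the data were examined called for a count test if all genes were given, and for the authors' deposited fold changes and adjusted p-values to be described if they were selected. Every listed gene has a p-value below 0.05 in the deposited table, so the latter was done. The number of genes behind the authors' adjustment was computed from the ratio of adjusted to unadjusted p-values at each rank and came to 19985, with 218 of 230 steps within 1 gene of it. The procedure returned 19985 on simulated p-values cut at 0.05. The deposited adjusted p is exactly 1 for 18 genes of low mean, at most 1.86 normalized counts, and these were treated as having no adjusted p.

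WT and KO groups and replicate numbers were taken from the sample titles. Group means and SDs over 4 libraries were computed from the normalized values. The same-numbered libraries are not stated to be paired. Libraries of one group differed by more than counting noise, with a chi-square per degree of freedom of at least 18.1, so none were merged; repeat preparations of 1 tumour could differ as much, so this does not show separate samples.

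As alternatives, recovered reads of the listed genes were refitted with edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma 3.58.1 (limma-trend on log2 of the normalized value plus 1, or plus 0.1) in R 4.3.3, with the deposited size factors, and Benjamini-Hochberg adjustment over 19985 genes. Their spread is estimated from selected genes, so the refits describe how far the listed values bear another test and are not an independent test. The edgeR step was tested on simulated data with 1428 genes and 4 against 4 libraries. It recovered 67.0% of 94 genes changed 2-fold and 91.5% of 106 genes changed 4-fold, and called 5 of 1228 unchanged genes. Those calls were adjusted over the 1428 simulated genes and used a set spread. The recovered shares therefore do not apply to the refits of the deposited values, which were adjusted over 19985 genes.

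Named genes followed a rule fixed before the data were examined. Per direction it takes the 10 largest absolute log2 fold changes among genes with an adjusted p below 0.05, separate groups and a mean at or above the median over the listed genes (179.7 normalized counts). It adds, from each of 36 fixed lists (631 symbols, 62 of them listed), up to 4 members past the threshold or otherwise up to 2 with the smallest p. Genes named outside this rule were chosen after their values were seen: Bank1, Ighg2b and Tm4sf4, symbols that only fill a count of listed members, and in the closing section those of the 9 added families, Sycn, Pigr, Lypd8 and Ighd. The values of some genes are not reported here. List symbols were matched by exact name or, failing that, by an unambiguous RefSeq synonym. Those of the ribosomal protein family were matched by exact name alone. List direction was tested with Fisher's exact test against the other listed genes and adjusted over the 25 lists with a listed member. Camera was run among the listed genes on the 9 fixed lists with at least 3 listed members.

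For miR-29 sites, the 3′ UTR was the part of a GENCODE M21 protein-coding transcript beyond its stop codon, and the longest per symbol was searched for TGGTGCT, the match to the miR-29 seed. Of 1097 listed protein-coding genes, 1030 (93.9%) were searched. Permutations used 100000 resamples. Scripts were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives tried were stricter thresholds, leaving out each library, a replicate block, other tools and pseudocounts, other site definitions, and gene set tests with a preset or estimated correlation; the closing section gives their effect.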

Results

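RNA sequencing was used to compare colon tumours of 4 wild-type (WT) libraries with colon tumours of 4 libraries from mice labelled as lacking miR-29ab1 in the intestinal epithelium (KO), all on the C57BL/6N background. The tumours had been induced with azoxymethane, a colon carcinogen, and dextran sodium sulfate, which injures the colonic lining. The values are gene counts divided by size factors (normalized counts) for 1428 genes, each with an unadjusted p below 0.05 in the authors' deposited table. The deposited table was therefore a selected list, and fold changes in such a list are larger on average than in an unselected one. The normalized counts of these genes corresponded to between 1202677 and 2180787 whole reads per library, a sum over the listed genes that is not the library depth, which is not given in the sources used here. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

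The first comparison asked which transcripts differed between KO and WT tumours. By the authors' deposited table, 6 genes rose and 2 fell in KO tumours at an adjusted p below 0.05. Their adjusted p-values from DESeq2 all lay close to that threshold, from 0.0437 to 0.0461. The genes that rose were Capn5, a calcium-dependent protease; Sh3rf2, a RING and SH3 domain protein; Lrmp, a lymphoid-restricted membrane protein; Fosb, an immediate-early transcription factor; Bank1, a B cell scaffold protein; and Ighg2b, an immunoglobulin heavy chain constant region. The genes that fell were Gstm7, a glutathione S-transferase, and Tm4sf4, a tetraspan membrane protein.

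Capn5 was the most abundant of the 8, at 5227 ± 231 normalized counts in KO (SD, n = 4) and 3148 ± 430 in WT (SD, n = 4). Its log2 fold change in the authors' deposited table was 0.73, with an adjusted p of 0.0437 from DESeq2. Sh3rf2 stood at 358.7 ± 84.6 in KO and 140.7 ± 39.1 in WT, and the authors' deposited table gives a log2 fold change of 1.35. Lrmp reached 915 ± 190 in KO against 428.7 ± 98.4 in WT, with a log2 fold change of 1.09 in the authors' deposited table. Fosb, which was also the one listed member of the fixed list of RNA quality and stress genes, stood at 275 ± 109 in KO and 94.3 ± 22.2 in WT, with a log2 fold change of 1.54 in the authors' deposited table. Gstm7 stood at 426 ± 136 in KO and 970.1 ± 54.3 in WT, a log2 fold change of -1.19 in the authors' deposited table. These 5 genes met the rule for named genes, and in each the 4 KO libraries lay on one side of the 4 WT libraries.

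The other 3 were less abundant or overlapped between groups, and they are named because they complete the 8. Bank1 had 52.8 ± 57.4 normalized counts in KO and 2.80 ± 1.93 in WT, and its log2 fold change in the authors' deposited table was 4.24. Its KO libraries ranged from 9.64 in replicate 1 to 134.1 in replicate 4. Ighg2b had 352 ± 128 in KO and 111.6 ± 43.0 in WT, with a log2 fold change of 1.66 in the authors' deposited table; KO replicate 3, at 167.3, lay below WT replicate 3, at 174.9. Tm4sf4 had 23.3 ± 6.25 in KO and 96.4 ± 47.5 in WT, with a log2 fold change of -2.05 in the authors' deposited table. A DESeq2 refit of the recovered reads gave standard errors of the log2 fold change of 0.14 for Capn5, 0.27 for Gstm7 and 1.01 for Bank1. In the coordinates of the table, whose gene identifiers belong to the C57BL/6NJ strain annotation, Capn5 lies on chromosome 7 from 104760981 to 104819759, Gstm7 on chromosome 3 from 113534664 to 113540147, and Bank1 on chromosome 3 from 143825953 to 144108848. All 3 are annotated there as protein-coding genes on the minus strand.

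**Figure D1:**
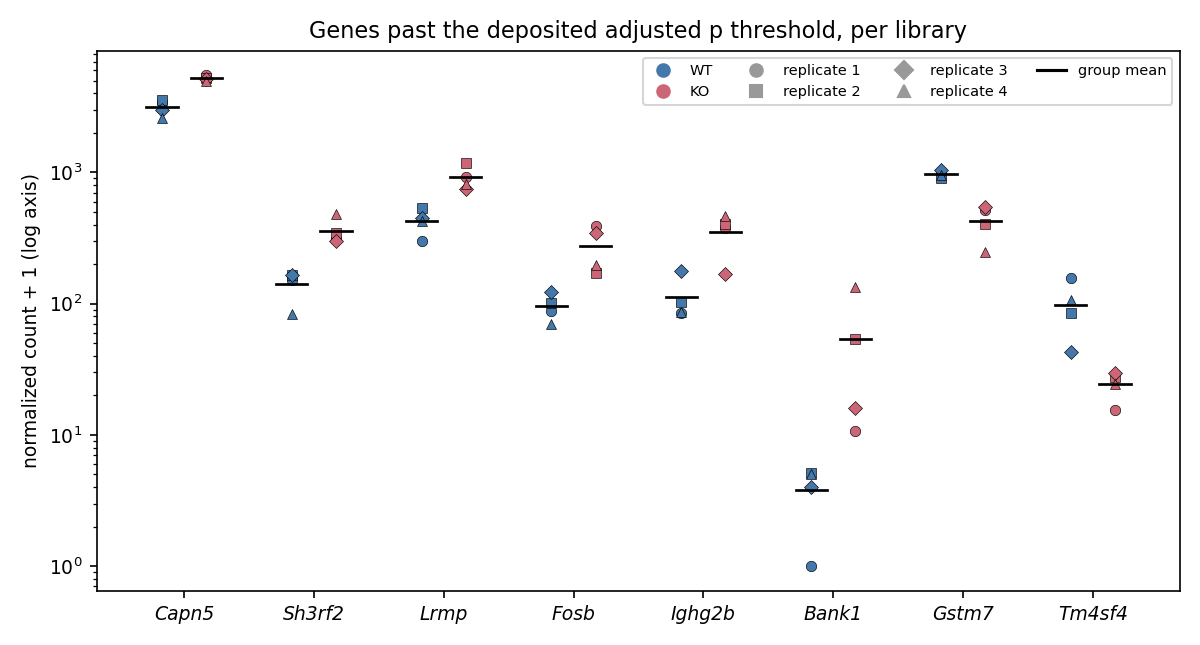
Normalized count plus 1 (log axis) of the 8 genes past an adjusted p of 0.05, one point per library, with WT in blue, KO in red, marker shape for the replicate number and a line at each group mean. Capn5 separates the groups with little spread, at 3148 in WT and 5227 in KO, whereas Bank1 ranges from 9.64 to 134.1 among the KO libraries.

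Beyond these 8 genes, 829 of the 1428 listed genes were higher and 599 lower in KO by the authors' deposited table. The median log2 fold change there was 1.00 among those higher and -0.88 among those lower. The 4 KO values lay wholly on one side of the 4 WT values in 638 genes, 342 higher and 296 lower; chance gives 2.86% for an unselected gene. The deposited adjusted p-values imply an adjustment over 19985 genes, of which 999.2 would fall below an unadjusted p of 0.05 with no effect at all. The authors' deposited table holds 1410 such genes, 1.41 times as many, and a further 18 whose adjusted p is set to 1. At an adjusted p below 0.1 the authors' deposited table holds 23 genes. An edgeR quasi-likelihood refit of the recovered reads put 1112 of the listed genes below an unadjusted p of 0.05 with the same sign, and 0 below an adjusted p of 0.05, so the call of the 8 genes rests on DESeq2.

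KO replicate 4 stood apart among the listed genes. It was the highest KO library in 622 of the 829 genes listed higher (75.0%) and the lowest in 355 of the 599 listed lower (59.3%), where equal shares would give 25%. Without it, 741 listed genes stayed below an unadjusted p of 0.05 with the same sign in the edgeR refit, 385 higher and 356 lower. More stayed without KO replicates 1, 2 and 3, at 854, 869 and 918. Among the WT libraries, 643 stayed without replicate 4, 660 without replicate 1, 740 without replicate 2 and 895 without replicate 3. Leaving out KO replicate 4 moved log2 fold changes furthest from the deposited ones, by a median of 0.18, against 0.072 to 0.12 for the other libraries. WT replicate 4 was the highest WT library in 304 of the 599 genes listed lower (50.8%) and the lowest in 335 of the 829 listed higher (40.4%). None of the 8 genes depended on it for its direction: without KO replicate 4, the mean of the other 3 KO libraries was 1.69 times the WT mean for Capn5, 9.21 times for Bank1 and 0.50 times for Gstm7.

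**Figure D2:**
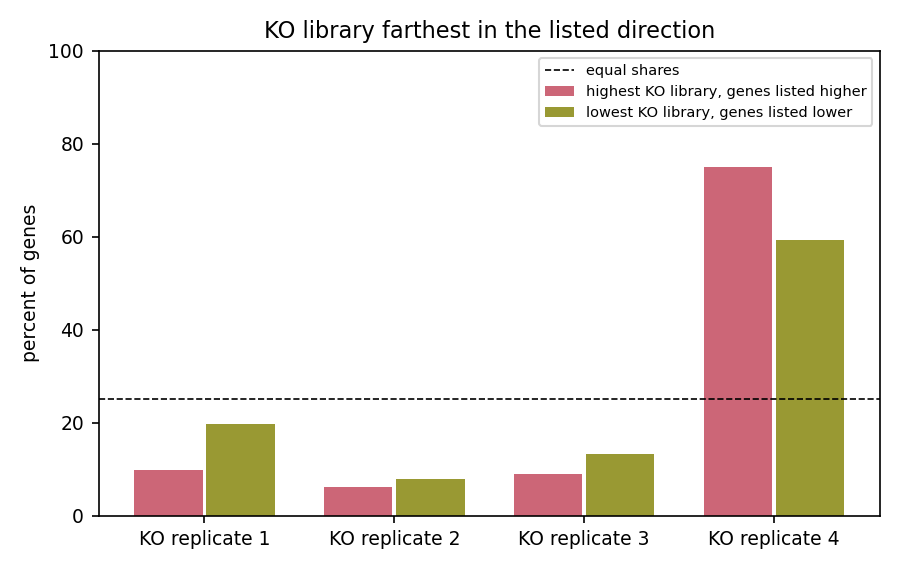
Percent of the listed genes (y axis) in which each KO library (x axis) was the highest of the 4, among genes listed higher, or the lowest, among genes listed lower; the dashed line marks equal shares of 25%. KO replicate 4 takes 75.0% and 59.3%.

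The second comparison took 36 gene lists fixed before the data were examined and asked whether their listed members lay mostly on one side. Chance would list 7.06% of the members of any list. The B and plasma cell list had 12 of its 20 members listed, all 12 higher in KO and none past an adjusted p of 0.05 over all genes, while 11 passed when adjusted over the list alone. Chance would list 1.41 members. Among the 12 were the B cell receptor components Cd79a, Cd79b, Ighm and Ighd and the surface proteins Cd22, Ms4a1 and Cr2. Also among them were Fcrla, the kinase Blk, and the transcription regulators Pax5 and Pou2af1. Cd79a stood at 151 ± 160 normalized counts in KO (SD, n = 4) and 20.6 ± 9.92 in WT, and Cd22 at 116 ± 128 in KO and 16.6 ± 4.62 in WT. The authors' deposited table gives them log2 fold changes of 2.87 and 2.80 and adjusted p-values from DESeq2 of 0.0648 and 0.0610. The 8 members that were not listed include the plasma cell genes Jchain, Mzb1, Sdc1 and Igha.

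By Fisher's exact test, two-sided, of higher against lower members, the B and plasma cell list was the one list of the 25 with a listed member that passed, at a Benjamini-Hochberg adjusted p of 0.0479. Membership among the listed genes was also in excess of chance, with an adjusted hypergeometric p of 3.87e-08 that takes the members as independent. They were not: camera, a gene set test, estimated a correlation of 0.775 among the listed members. Run among the listed genes alone, camera tests direction and not membership. It gave this list an adjusted p of 0.0741 with a preset correlation of 0.01 and an adjusted p of 0.822 with the estimated correlation. The call was lost in the edgeR refit: among the genes that stayed below an unadjusted p of 0.05 there with all 8 libraries, 10 members were higher and none lower, with an adjusted p of 0.134 by Fisher's exact test. In edgeR refits without 1 library that adjusted p ran from 0.0522 without WT replicate 4 to 0.959 without KO replicate 2, and was 0.22 without KO replicate 4. The members kept in those refits were all higher, from 6 without WT replicate 2 or WT replicate 3 to 12 without KO replicate 1. The p-value also depends on how many members and other genes are kept, so a higher value does not show members turning lower. For Cd79a the KO mean without KO replicate 4 was 3.62 times the WT mean, and for Cd22 3.15 times. The KO libraries differed widely in these genes. The median of the 12 ratios to the WT mean was 1.07 in KO replicate 1, 5.29 in replicate 2, 2.39 in replicate 3 and 16.5 in replicate 4, and KO replicate 1 exceeded every WT library in 3 of the 12 genes while replicates 2 and 4 did so in all 12.

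**Figure D3:**
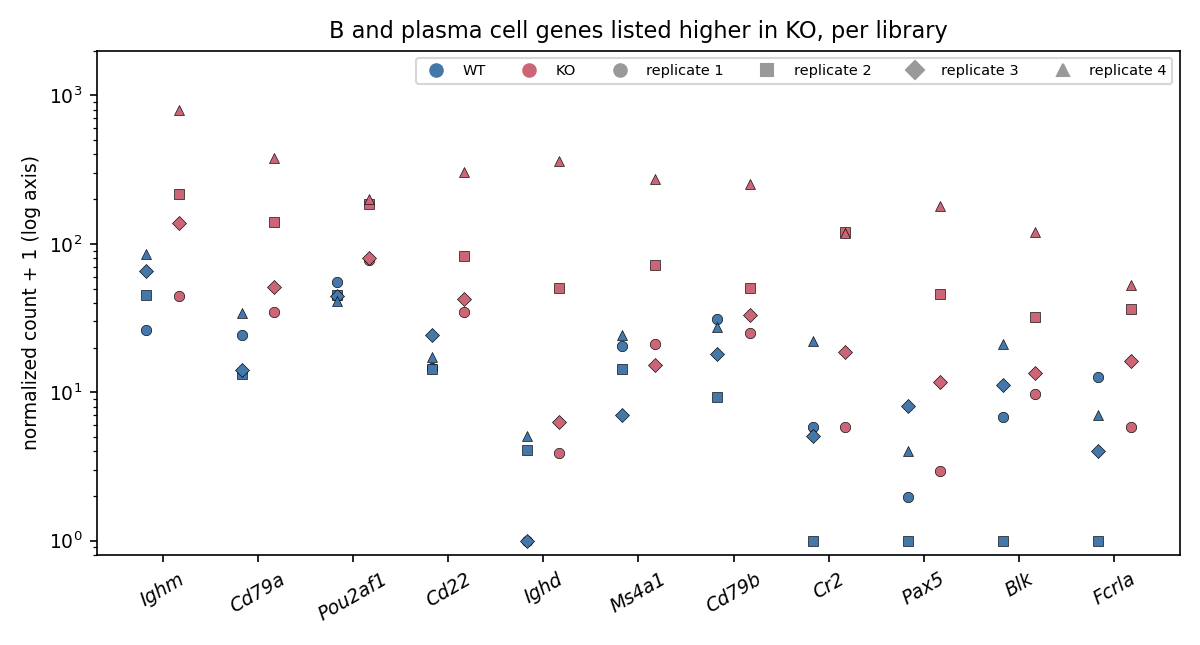
Normalized count plus 1 (log axis) of 11 listed members of the B and plasma cell list, one point per library, with WT in blue, KO in red and marker shape for the replicate number. KO replicates 2 and 4 lie above every WT library in each gene shown, and KO replicate 1 does so in 3.

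Of 24 genes of T cell and cytotoxic identity, 2 were listed higher and 1 lower, and 21 were not listed, against 1.69 that chance would list. Trbc1, a T cell receptor beta constant region, had 85.5 ± 20.7 normalized counts in KO (SD, n = 4) and 50.4 ± 7.21 in WT. Cd8b1, a chain of the CD8 co-receptor, had 5.77 ± 5.25 in KO and 0.253 ± 0.506 in WT, too few to carry a fold; WT replicate 4 held all the WT counts. The third was Eomes, a T-box transcription factor, listed lower. Among 16 helper and regulatory T cell genes, 4 were listed where chance would list 1.13, with a hypergeometric p adjusted over the lists of 0.306. Of these, 2 were higher, with Cd4 at 49.3 ± 26.1 in KO and 19.6 ± 4.87 in WT, and 2 lower, with Il2ra at 16.5 ± 6.16 in KO and 33.7 ± 12.5 in WT. Of 14 checkpoint genes Btla alone was listed, at 52.1 ± 66.5 in KO and 8.29 ± 3.12 in WT, with 148.7 in KO replicate 4; without that library the KO mean was 2.41 times the WT mean. None of the genes in these 3 lists passed an adjusted p of 0.05 over all genes.

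The series title names fucosylation and Ras signalling, and both lists were sparse. Of 18 fucosylation genes, 2 were listed, both higher and neither past the adjusted threshold. Slc35c1, the Golgi GDP-fucose transporter, had 4547 ± 1005 normalized counts in KO (SD, n = 4) and 3167 ± 689 in WT, and Fuca1, a lysosomal fucosidase, had 5245 ± 1236 in KO and 3876 ± 168 in WT. The authors' deposited table gives them log2 fold changes of 0.52 and 0.44 and DESeq2 adjusted p-values of 0.696 and 0.698. Without KO replicate 4 the KO mean was 1.28 times the WT mean for Slc35c1 and 1.22 times for Fuca1. The groups overlapped in Slc35c1, with WT replicate 3 at 3787 above KO replicate 1 at 3771. Chance would list 1.27 members. Of 31 Ras and MAPK genes, 3 were listed, all higher, among them Fos at 3071 ± 588 in KO and 1909 ± 296 in WT, where chance would list 2.19. Neither list passed the exact test of direction, each with an adjusted p of 0.854.

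Of 24 inflammatory cytokine genes, 3 were listed, all lower, where chance would list 1.69, and the exact test of direction gave an adjusted p of 0.854. They were Il1b, at 516 ± 311 normalized counts in KO (SD, n = 4) and 1158 ± 112 in WT, Ccl4, at 9.71 ± 9.60 in KO and 28.8 ± 9.31 in WT, and Ccl3. The KO mean of Ccl4 was 5.09 without KO replicate 2. The mast cell proteases Mcpt1, at 178 ± 164 in KO (104.1 without KO replicate 1) and 1069 ± 945 in WT, and Tpsb2, at 30.9 ± 22.3 in KO and 123.2 ± 71.2 in WT, were the 2 listed members of 14 mast cell and eosinophil genes. Mpo, a neutrophil granule enzyme, was 0 in the 4 KO libraries and reached 23.3 in WT replicate 4. Fscn1, listed from the dendritic cell genes, stood at 428 ± 233 in KO and 857 ± 364 in WT. The MHC class II list had 2 members listed higher, the accessory chains H2-Ob, at 92.3 ± 128 in KO and 11.4 ± 9.45 in WT, and H2-Oa, at 16.0 ± 17.1 in KO and 0.982 ± 1.38 in WT. Zbp1, from the interferon response list, stood at 1437 ± 1705 in KO and 522 ± 193 in WT, with 3982 in KO replicate 4. Without KO replicate 4 the KO mean was 2.53 times the WT mean for H2-Ob, 8.72 times for H2-Oa and 1.13 times for Zbp1. The WT mean was 7.07 for H2-Ob without WT replicate 4 and 0.337 for H2-Oa without WT replicate 1. None of these passed the adjusted threshold over all genes.

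Of 25 colonocyte genes, 4 were listed higher and 1 lower, with the brush border protein Cdhr5 at 10720 ± 5408 normalized counts in KO (SD, n = 4) and 6194 ± 558 in WT, and the protease Mep1a at 1534 ± 1945 in KO and 449 ± 256 in WT. Without KO replicate 4 the KO mean of Cdhr5 was 1.29 times and that of Mep1a 1.26 times the WT mean. Of 18 enteroendocrine and tuft cell genes, 4 were listed, all higher, with Chgb at 766 ± 772 in KO and 278 ± 113 in WT and Neurod1 at 30.4 ± 40.6 in KO and 7.85 ± 4.38 in WT. Leaving out KO replicate 4 gave KO means of 1.39 times the WT mean for Chgb and 1.31 times for Neurod1. The stem cell regulator Ascl2 was the one listed gene of the stem cell and Wnt list, at 767.2 ± 92.3 in KO and 1060 ± 151 in WT. Birc5, at 641 ± 142 in KO and 912 ± 159 in WT, and Top2a, at 4000 ± 627 in KO and 5338 ± 862 in WT, were the listed members of 22 proliferation genes, both lower.

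Of 16 fibroblast genes, 2 were listed higher and 1 lower. Dpt, at 158.0 ± 33.6 normalized counts in KO (SD, n = 4) and 84.1 ± 28.3 in WT, and Mfap5, at 11.8 ± 5.67 in KO and 3.02 ± 2.49 in WT, were the 2 listed higher. Single members were listed higher from the endothelial, smooth muscle and enteric neuron and glia lists. Lyve1 stood at 84.1 ± 55.7 in KO and 38.6 ± 11.2 in WT, Myocd at 12.6 ± 9.02 in KO and 2.97 ± 2.86 in WT, and Chat, which is made by enteric neurons and by tuft cells, at 13.2 ± 17.9 in KO and 0 in the 4 WT libraries. The KO mean of Chat was 4.51 without KO replicate 4, and the WT mean of Myocd 1.69 without WT replicate 1. Of 19 fatty acid oxidation and PPAR genes, 2 were listed higher and 1 lower. Ppara stood at 50.5 ± 41.5 in KO and 19.1 ± 10.6 in WT, Angptl4 at 28.7 ± 21.4 in KO, 19.0 without KO replicate 1, and 67.3 ± 26.7 in WT. Of 23 xenobiotic and bile genes, 2 were listed, both higher. The drug efflux pump Abcb1a stood at 3951 ± 5268 in KO and 1198 ± 689 in WT, with 11805 in KO replicate 4, and Nr1i3 at 13.3 ± 4.36 in KO and 4.53 ± 2.42 in WT. With KO replicate 4 left out, the KO mean was 1.57 times the WT mean for Ppara and 1.11 times for Abcb1a. No member was listed in 11 lists, those of macrophages, MHC class I, adipocytes, erythroid cells, goblet cells, ectopic small intestine and stomach, squamous skin, cholesterol synthesis, glycolysis and hypoxia, fructose and mannose metabolism, and Y-linked genes.

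The third comparison asked whether predicted miR-29 targets lay higher in KO tumours, since a microRNA lowers the transcripts it binds. Among 1030 listed protein-coding genes with an annotated 3′ untranslated region (UTR), 167 carried the miR-29 seed match in the longest one. Of these, 115 were listed higher in KO (68.9%), against 492 of 863 genes without a site (57.01%), an odds ratio of 1.67 with p = 0.00453 by Fisher's exact test, two-sided. The genes listed higher also had longer 3′ UTRs, with a median of 1516 bases against 708 bases for those listed lower, and longer UTRs hold more sites of any kind. Within 5 groups of equal size by 3′ UTR length the excess was gone: 116.8 site genes were expected to be higher and 115 were, with a permutation p of 0.765 and an odds ratio of 0.93 (95% interval 0.63 to 1.37). Of 139 other arrangements of the same 7 bases, 69 gave an odds ratio at least as large. Before stratification, the genes that stayed below an unadjusted p of 0.05 in the edgeR refit of all 8 libraries gave an odds ratio of 1.88 with p = 0.00291 by Fisher's exact test. In edgeR refits without 1 library the odds ratio stayed above 1, but the Fisher's exact p was 0.0516 without WT replicate 1, 0.0865 without WT replicate 2, 0.28 without WT replicate 4 and 0.0729 without KO replicate 3.

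**Figure D4:**
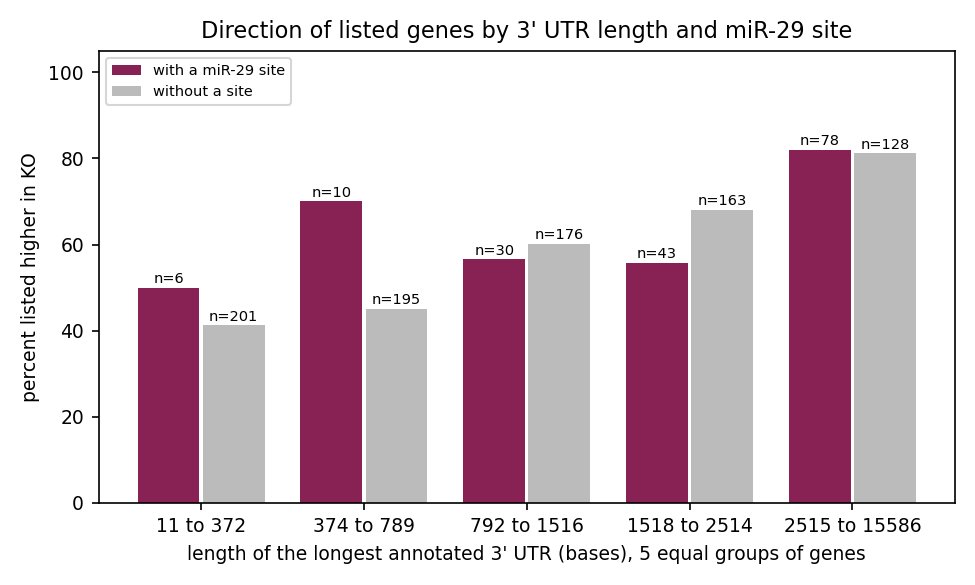
Percent of the listed protein-coding genes that were higher in KO (y axis), for genes with and without a miR-29 seed match, in 5 groups of equal size by the length of the longest annotated 3′ UTR in bases (x axis); n is the number of genes in each bar. The percentage rises with UTR length in genes without a site, from 41.3% to 81.3%, and in the group with the longest UTRs it is 82.1% with a site.

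Of 24 fixed miR-29 targets outside the matrix, 2 were listed, both higher and neither past the adjusted threshold. Hdac4, a histone deacetylase, stood at 805.5 ± 7.59 normalized counts in KO (SD, n = 4) and 665.0 ± 44.8 in WT, with the 4 KO libraries above the 4 WT libraries. Klf4, an epithelial transcription factor, stood at 7078 ± 7375 in KO and 2901 ± 1453 in WT, with 18058 in KO replicate 4; without that library the KO mean was 1.18 times the WT mean. Of 24 matrix targets, Col7a1 alone was listed, lower, at 131.2 ± 76.9 in KO and 351 ± 314 in WT; without WT replicate 4 the WT mean was 215.6. The targeted microRNA genes, their host transcript and Vil1 were not analysed here, so the genotype labels had no check from the targeted locus.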

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

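The tests of KO replicate 4 in this part were chosen after the result was seen. Among the 140 groups of 4 library values examined, 19 held a library far from the other 3, a gap that chance gives in about 1 of 20 groups of normally spread values. That rate does not apply here, because the genes were listed for their difference between KO and WT. Some, among them Lypd8, Pigr, Sycn, Hnf4a, Hnf4g, Per2 and Ighd, were also named after their values were seen. In 15 of the 19 that library was KO replicate 4. It was the highest at 243970 normalized counts of Lypd8, 105328 of Pigr, 29148 of Sycn, 22661 of Hnf4a, 18826 of Cdhr5, 18058 of Klf4, 11805 of Abcb1a, 4431 of Mep1a, 3982 of Zbp1, 2162 of Per2, 512.7 of Hnf4g, 361.1 of Ighd, 282.8 of H2-Ob, 91.0 of Neurod1 and 88.1 of Cd4. In the WT group, replicate 4 stood apart at 12458 normalized counts of Hnrnpm, 23.3 of Mpo and 1.01 of Cd8b1, and replicate 1 was lowest at 5904 of Hnf4a.

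The genes in which KO replicate 4 stood apart include epithelial genes such as Lypd8 and Cdhr5, the pancreatic and gut secretory gene Sycn, and the B cell gene Ighd. An unusual size factor is argued against by its value of 1.02, which lies within the range of the other 7 libraries. Depth itself is not given, so a depth effect was not examined. The listed genes held 2180787 recovered reads in KO replicate 4, against at most 1533770 in any other library. A wrong scaling of that library, such as from a few genes taking most of the counts, would shift its genes one way, whereas it was both the highest in most genes listed higher and the lowest in most listed lower. Over scaling factors from 0.25 to 4 on that library, the larger of these shares never fell below 67.4%. A different mix of cells in that tumour, a different site along the colon, and a biological response that varies between animals stay open, as untested here. A length-dependent bias of that library stays open too. Among the listed genes its slope of log2 level on log2 gene length was 0.18, against 0.040 to 0.12 in the other KO libraries. WT replicate 4 lay at the other end, at -0.18, against -0.094 to -0.063 in the other WT libraries.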

How the results depend on the processing

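The edgeR refit of all 8 libraries on recovered reads, the counts of listed genes under each refit, the lists and miR-29 sites among genes kept in that refit, list membership against all genes, camera with a preset correlation and the UTR length permutation were added after seeing the data. The count of 8 genes past an adjusted p of 0.05 in the authors' deposited table became 7 with an absolute log2 fold change above 1 and 0 at an adjusted p below 0.01. It became 37 in the DESeq2 refit, which kept all 8, and 0 in the edgeR refit, in limma-trend with a pseudocount of 1 or 0.1 and in the edgeR refit without each library in turn (0 to 0). Each of the 8 kept its direction in all 13 refits and an unadjusted edgeR p below 0.05 in all 8 fits that left out a library, the highest being 0.0108 for Bank1. Of the 1428 listed genes, 1112 stayed below an unadjusted p of 0.05 with the same sign in the edgeR refit, 1355 with DESeq2, 1027 and 984 with limma-trend at pseudocounts of 1 and 0.1, and 643 to 918 in edgeR without each library in turn. With the replicate block in edgeR these counts were 0 past the adjusted threshold and 559 below the unadjusted one. Same-numbered libraries did not deviate together (correlations from -0.24 to 0.05, and 1 of the 8 libraries correlated best with its own number), so the numbers were not taken as pairs.

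The 1 fixed list past the threshold became 0 lists, and the adjusted p of the B and plasma cell list rose from 0.0479 to 0.0508 among genes with an absolute log2 fold change above 1, where fewer genes were compared. It was 0.0741 in camera with a preset correlation (0 lists), 0.822 with an estimated correlation (0 lists) and 0.134 in the edgeR refit of all 8 libraries (0 lists), so the call was lost in the refit before any library was left out. Within edgeR it was 0.306 with the replicate block (0 lists) and 0.0522 to 0.959 without each library in turn (0 to 0 lists). The members kept in each refit were all higher in KO, with 10 kept in the edgeR refit of all 8 libraries and 8 with the replicate block. These exact test p-values therefore also depend on how many members and other genes were kept. Camera with the preset correlation and the replicate block gave 0.0125. The miR-29 odds ratio of 1.67 was 2.14 with the 8-base site alone (p = 0.0685 by Fisher's exact test), and 2.11 in genes at or above the median level. Within edgeR it was 1.88 with all 8 libraries, 1.61 with the replicate block (p = 0.148 by Fisher's exact test), and 1.37 to 2.49 without each library in turn; within 5 groups of UTR length the permutation p was 0.765. Blocked values differ from the deposited ones in tool and model, leave-one-out values in tool and samples, and the cause was not tested. Over single named genes and refits, 786 values kept their direction and side of the threshold, 96 fell short of it with the same direction, all of them of the 8 genes, and 2 came past it. Not run were TMM scaling and filters on low counts, which need all genes, fry, whose answer is set by the selection of the list, and the targeted locus, which was not analysed here. As reads cover the listed genes alone, the effect of depth was not examined.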

Other observations

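Besides the fixed lists, 9 families were chosen after their values were seen, so their counts describe the listed genes and are not independent evidence. Some members also belong to fixed lists, among them Chat in the tuft cell family and Ccl3 in the CC chemokines, so these counts overlap with those above. Chance would list 7.06% of the members of a family. Genes of B cell follicles followed the B and plasma cell list: 15 of 20 were listed higher and 1 lower, among them the follicle homing receptor Cxcr5, at 42.4 ± 57.6 normalized counts in KO (SD, n = 4) and 3.49 ± 2.64 in WT, its ligand Cxcl13, at 137 ± 123 in KO and 52.2 ± 20.5 in WT, and the IgM receptor Fcmr, at 41.3 ± 61.4 in KO and 2.00 ± 2.19 in WT. The KO mean without KO replicate 4 was 4.15 times the WT mean for Cxcr5, 1.57 times for Cxcl13 and 5.50 times for Fcmr, whose WT mean fell to 0.986 without WT replicate 4. Of 16 transcription factors of colonic epithelium 6 were listed, all higher, including Hnf4a at 12570 ± 6735 in KO and 7214 ± 882 in WT and Hnf4g at 256 ± 171 in KO and 115.2 ± 35 in WT; KO replicate 4 was far above the other KO libraries in both, and without it the KO mean was 1.28 and 1.48 times the WT mean. Pigr, the epithelial carrier of secreted immunoglobulin, stood at 48225 ± 38242 in KO and 23482 ± 5488 in WT, and the KO mean was 1.24 times the WT mean without KO replicate 4. Of 19 circadian clock genes, 5 were listed higher and 1 lower, with Arntl at 826 ± 601 in KO and 368 ± 210 in WT and Per2 at 1079 ± 729 in KO and 547 ± 155 in WT; without KO replicate 4 the KO mean was 1.44 times the WT mean for Arntl and 1.31 times for Per2. Of 18 tuft cell genes 4 were listed, all higher, with Gnat3 at 27.9 ± 38.7 in KO and 3.50 ± 2.36 in WT, a KO mean of 2.53 times the WT mean without KO replicate 4.

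Lower in KO were 6 of 20 CC chemokines and none higher, with Ccl11 at 18.1 ± 14.2 normalized counts in KO (SD, n = 4) and 49.7 ± 17.2 in WT, Ccl17 at 4.42 ± 2.46 in KO and 13 ± 5.85 in WT, and Ccl24 at 9.91 ± 7.29 in KO and 30.3 ± 10.7 in WT. Of 76 ribosomal protein genes 7 were listed, all lower, near the 5.36 that chance would list, with Rpl7 at 14095 ± 742 in KO and 17395 ± 1722 in WT and Rps9 at 14938 ± 853 in KO and 21374 ± 7390 in WT. Of 20 hnRNP genes 4 were listed lower, with Hnrnpm at 4999 ± 632 in KO and 7750 ± 3155 in WT. Of 13 Sm and related splicing proteins 4 were listed lower, with Snrpe at 570 ± 131 in KO and 1249 ± 716 in WT. Of 8 chaperonin subunits 3 were listed lower, with Cct2 at 6189 ± 646 in KO and 8247 ± 1355 in WT. WT replicate 4 was the highest WT library for Rps9 (32234, next 19400), Hnrnpm (12458, next 6599), Snrpe (2276, next 1201) and Cct2 (10249, next 7883). It was not the highest for Rpl7. Part of the difference in Rps9, Hnrnpm, Snrpe and Cct2 thus rests on that library. None of the genes named in these families except Bank1 passed the adjusted threshold in the authors' deposited table, and with an estimated correlation in camera the 9 added lists had an adjusted p of at least 0.486.

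Both tests of the B cell pattern, the 3′ UTR length test and the count over other splits were chosen after the result was seen; the test of length slopes was chosen before. The listed B and plasma cell genes were higher in KO by a median log2 ratio of 2.66. KO replicate 4 was not the one library above WT: KO replicate 2 exceeded every WT library in 12 of the 12 genes (median 5.29 times the WT mean) and KO replicate 3 in 8 (2.39 times), while KO replicate 1 did so in 3 (1.07 times). Without KO replicate 4 the median log2 ratio was 1.47, with at least 0.74 when 1 more library was left out, all 12 ratios stayed above 1 and 7 genes had an unadjusted edgeR p below 0.05, but these genes were selected on this comparison. Over all 20 members, with the 8 unlisted ones counted as lowest, the median without KO replicate 4 was at least 1.03, and at least 0.18 with KO replicate 2 left out as well. These are floors and not estimates. The lower one leaves out KO replicate 2 as well, so it does not bear on KO replicate 4 alone. It shows that the floor without KO replicate 4 leans on KO replicate 2. Over all 20 members, whether the pattern goes beyond KO replicates 2 and 4 stays open. The 12 genes deviated together among the KO libraries, with a mean pairwise correlation of 0.935 across genes, against 0.33 (95% of sets from 0.0042 to 0.753) in 10000 random sets of other genes listed higher; without KO replicate 4 the values were 0.937 and -0.01 (up to 0.308). Among the WT libraries the correlation was 0.278, against the random sets there (median 0.098, 95% of sets from -0.062 to 0.418); KO and WT were not compared in this, and WT counts of these genes are low. The KO values are consistent with a difference in B cell content between the sampled pieces, but a regulation shared by these genes predicts the same and stays open. So does whether such a difference comes from the genotype or from lymphoid follicles in some pieces, which are common in colon.

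Genes with a miR-29 site were more often listed higher in KO. The 3′ UTR length may account for the whole excess, with a permutation p of 0.765 within 5 groups of length, and 61 of 139 other arrangements of the same bases gave a Fisher p below 0.05. Listed protein-coding genes that were higher in KO were longer, with a median gene length in the table of 4564 bases against 2864 bases, and this held without the ribosomal, splicing and chaperonin families, at 4564 against 2897 bases. A length-dependent bias of single libraries cannot be told apart from a group difference here: the widest range of length slopes within a group was 0.66 of the difference between the group means, and the genes were selected on that difference.

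For the count of listed genes, the real grouping gave 1112 genes below an unadjusted p of 0.05 in the edgeR refit, and 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many, the real one; the highest of the other splits gave 307. Since the genes were selected by the real grouping, this says nothing on whether chance can be excluded.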
